A study of Mus musculus with 7 samples.

How the data were processed

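BRG1 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse CD4+ T helper cells. BRG1 is the ATPase of the SWI/SNF chromatin remodelling complex, and an antibody raised against it, named J1, was used. Per the labels, naive CD62L+ cells, 95% pure, were taken from the spleen and lymph nodes of Balb/c mice aged 4 to 6 weeks. Th1 cells were differentiated with IL-12 at 1 ng/ml and Th2 cells with IL-4 at 10 ng/ml. Th17 cells were differentiated with IL-6 at 100 ng/ml, IL-1β at 10 ng/ml, TGF-β at 1 ng/ml and IL-23 at 10 ng/ml. Stimulated cells received PMA at 50 ng/ml and ionomycin at 500 ng/ml for 1.5 h, a pharmacological substitute for signalling through the T cell receptor. Chromatin was crosslinked with formaldehyde and fragmented with micrococcal nuclease and sonication. Libraries were amplified over 18 PCR cycles, size-selected at 250 to 300 bases and sequenced on an Illumina Genome Analyzer II.

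The authors deposited 1 list of aligned reads per library, with the chromosome, start, end and strand of every read and no score, count or signal of their own. Each read was 34 bases long, and several reads at 1 position stood as several lines. The genome build was mm9, per the submitters' processing notes. The last read base on chromosome 1 was 197194862 in the input, while the last gene end on that chromosome in the GRCm38 gene table was 195291439. The builds differ, so coordinates of that table were not used, and no gene names are attached to regions. The aligner, its version and its filters are not given in the sources used here.

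The series holds 7 libraries: BRG1 libraries of naive cells, of Th1 and Th2 cells at rest and of Th1, Th2 and Th17 cells after stimulation, and an input library of CD4+ T cell DNA without immunoprecipitation. Each group has 1 library, so no difference has a replicate check, no p-value is given, and every ratio compares libraries, not conditions. Intervals are 95% Clopper-Pearson intervals. Those on reads cover counting error only, because PCR copies without molecular identifiers are not independent molecules. Those on percentages of regions take regions as independent trials. All choices below were fixed before the data were examined, except where a later choice is named.

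From the deposited reads, 1 read per start and strand was kept, chromosome Y was left out, and each 5′ end was moved 75 bp towards the centre of its fragment. The remaining distinct reads numbered 2071800 in naive, 1808000 in resting Th1, 1340208 in resting Th2, 3917492 in stimulated Th1, 4261900 in stimulated Th2, 7892944 in stimulated Th17 and 3531867 in input. Reads were counted in windows of 200 bp. A window was called where its count passed a Poisson tail of 1e-05 against the largest of the genome mean and the scaled input density in the surrounding 1, 5 and 10 kb. Called windows were joined over gaps of up to 1 window. For calling, each BRG1 library was thinned to 1340208 distinct reads, the number in resting Th2. The union of the regions of all 6 libraries was then counted with all distinct reads of each library.

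For each of 8 pairs of libraries, the ratio of RPM (reads per 1000000 distinct reads) was computed in every union region with at least 10 reads in the pair, with a conditional exact interval. A region was called higher or lower where the ratio was at least 3-fold and its interval left out 1. Where a library had 0 reads, the fold is given against a floor of 3 counts per library and written as a lower bound. The floor allows for the count of 0 only and not for the error of the other count, so the lower end of the exact interval, which allows for both, is given beside it. Because the ratio of total reads need not be the right scale, each split of higher and lower regions was repeated after division by the median ratio. The 5 highest and 5 lowest regions of each comparison, by the interval bound nearest 1, were set aside for naming by coordinates; the rule named genes first and fell back to regions because no mm9 annotation was used. Overlaps of calls between comparisons, subset-specific regions among stimulated cells, their clusters of at least 3 regions with gaps of up to 50 kb, regions called in all 6 libraries, and regions empty in a library were chosen after the data were examined.

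The steps were tested on simulated data. With 200 planted windows expecting 6 reads each, 66.5% were recovered and 4 false regions were called genome-wide; with 12 expected reads, 99% were recovered. In simulated pairs without any difference, the rule called 159 regions for naive against resting Th1, 156 for naive against resting Th2, 199 for resting Th1 against resting Th2, 249 for activation in Th1, 270 for activation in Th2, 224 for stimulated Th1 against stimulated Th2, 224 for stimulated Th17 against stimulated Th1 and 243 for stimulated Th17 against stimulated Th2. The counts of these pairs, and of the equal-depth pairs simulated below, were drawn around the observed reads of regions already called. They leave out that regions were called on reads that were then counted. The simulated numbers may thus understate the calls that arise without a difference. A simulated 10-fold difference was recovered in 62% of regions for activation in Th2, the lowest of the 8 comparisons, and in 95.5% for stimulated Th1 against stimulated Th2, the highest. A simulated 3-fold difference was recovered in 25% and 51% of regions in the same comparisons. These differences were planted in a single direction, higher after stimulation and higher in stimulated Th1. Recovery in the opposite direction was not simulated.

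The alternatives tried were all reads of each library, a threshold of 1e-08, all reads kept at repeated positions, no shift, the genome mean as the only background, ratios centred on their median, ratios scaled by 10 kb bins without regions, a 2-fold rule, at least 20 reads, and regions called on a random 50% of the reads and counted on the other 50%. Regions where both libraries held at least 0.5 times the input density, and libraries thinned to equal depth before counting, for activation also with ratios centred on their median, were added after the data were examined. Promoter shares, gene list medians and sequence motifs were planned and not run, since they need an annotation or a sequence of mm9, which were not used here. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.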

Results

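BRG1 ChIP-seq reads were compared between naive CD4+ T helper cells, Th1 and Th2 cells at rest, and Th1, Th2 and Th17 cells stimulated for 1.5 h with PMA and ionomycin, with 1 library per group and 1 input library. Th1, Th2 and Th17 cells are effector subsets of helper T cells that make different cytokines. The lists of aligned reads held 3533175 reads for naive, 2529147 for resting Th1, 2114977 for resting Th2, 4419697 for stimulated Th1, 4830623 for stimulated Th2, 8786251 for stimulated Th17 and 3807367 for input. Reads that repeated a start and strand made up 41.4% of the naive, 28.5% of the resting Th1 and 36.6% of the resting Th2 library. They made up 11.4% of stimulated Th1, 11.8% of stimulated Th2, 10.2% of stimulated Th17 and 7.23% of input. The unstimulated libraries were thus both shallower and more repetitive than the stimulated ones. All positions are on mm9, and every interval is a 95% interval that leaves out the spread between replicate libraries. Intervals on percentages of regions take regions as independent trials, which they are not.

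At equal depth and with 1 read kept per position, more regions were called in stimulated Th1 and Th2 cells than in the other libraries, and the fewest in naive cells. In that setting, 11278 regions were called in stimulated Th1, 10643 in stimulated Th2, 8298 in resting Th2, 6886 in resting Th1, 5739 in stimulated Th17 and 2909 in naive. Their own regions held 9.57% of the reads of stimulated Th1 (9.53 to 9.62) and 2.23% of the reads of naive (2.21 to 2.26). The input held 1.19% and 0.424% of its reads in the same regions. The median region was 1 window of 200 bp in every library. When the input took the place of the BRG1 library, 31 regions were called against stimulated Th1 and 138 against naive, which is 4.74% of the naive count. These counts depended on depth: with all distinct reads, stimulated Th17 had the most regions of any library, 42466, and naive had 5386. They also depended on repeated reads: with all reads kept at repeated positions, resting Th2 had the most regions, 30306, and stimulated Th17 the fewest, 15420, with 17064 in naive.

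**Figure D1:**
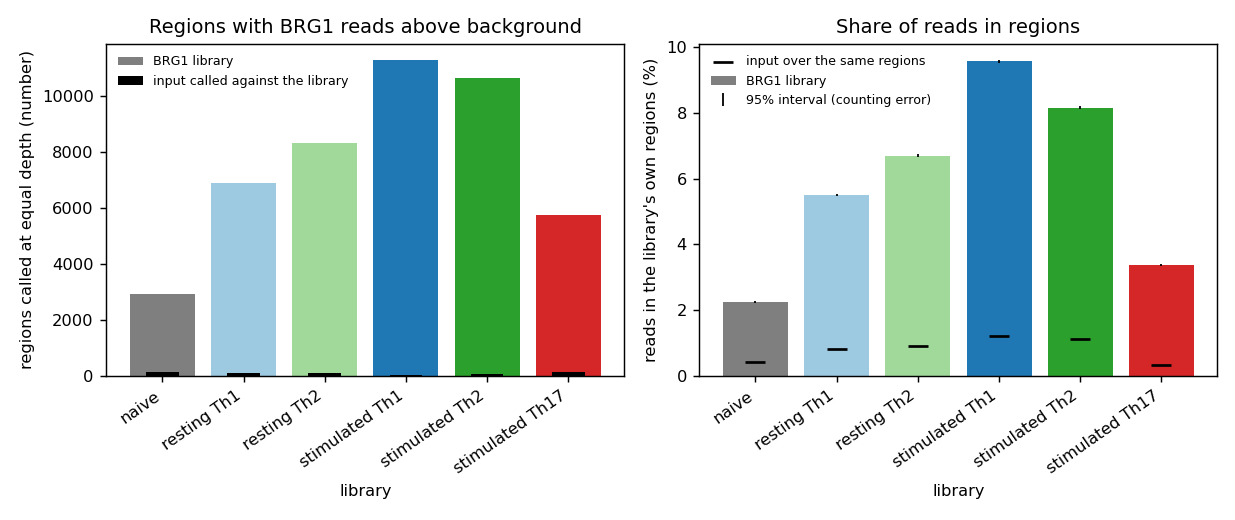
Left, the number of regions called per BRG1 library at 1340208 distinct reads each, with the number called when the input takes the library's place in black. Right, the percentage of each library's reads in its own regions with 95% intervals for counting error, and the percentage of input reads in the same regions as dashes. Stimulated Th1 has the most regions, 11278, and naive the fewest, 2909.

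Most regions were called in 1 library only, and by correlation the libraries resembled each other most within a state. The union held 25317 regions, of which 14352 were called in 1 library and 378 in all 6. A further 785 were called in the 3 stimulated libraries and in no other, and 175 in the naive and both resting libraries and in no other. Of the naive regions, 53.5% (51.7 to 55.3) shared at least 1 bp with a resting Th1 region, against 0.125% after shuffling. The shares were 49.6% between the resting libraries, 47.4% between stimulated Th1 and Th2, 40.8% of resting Th1 regions in stimulated Th1, and 36.3% of resting Th2 regions in stimulated Th2. Regions of stimulated Th17 were shared less than some pairs across states, 39.1% with stimulated Th1 and 34.9% with stimulated Th2. Across union regions, which are not independent replicates, Pearson's r of log2 RPM (1 read added) was 0.80 between stimulated Th1 and Th2, 0.72 between resting Th1 and Th2, 0.72 between naive and resting Th1, 0.68 between stimulated Th1 and Th17, and 0.60 both between naive and resting Th2 and between stimulated Th2 and Th17. Between unstimulated and stimulated libraries it was highest, 0.51, between naive and stimulated Th1. It was 0.48 between resting and stimulated Th1, 0.48 between resting and stimulated Th2, and lowest, 0.28, between resting Th2 and stimulated Th17. These correlations used all distinct reads, and the unstimulated libraries were the shallower ones. Low counts may lower r, so depth and state cannot be told apart here.

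The comparison of naive cells with resting Th1 cells addresses differentiation. BRG1 reads were higher in resting Th1 than in naive in 1513 of 9581 tested regions and lower in 76. Simulated pairs without any difference gave 159 calls, higher and lower together, so many of the 76 may be calls of that kind. Fewer regions differed at equal depth and more with all reads kept, as given below. On chromosome 11, 74773401 to 74773800, resting Th1 had 21 reads and naive 0, at least 8.02-fold higher (exact lower bound 5.97), with 6 reads in resting Th2. On chromosome 12, 55394201 to 55394600, resting Th1 had 29 reads and naive 1, a ratio of 33.2 (5.51 to 1357), and resting Th2 had 25. Naive was the higher library on chromosome 6, 99339201 to 99339600, with 23 reads against 2, a ratio of 10.0 (2.48 to 87.8), and on chromosome 2, 34760801 to 34761000, with 17 against 1. The 5 highest regions had 19 to 29 reads in resting Th1 against 0 or 1 in naive, and the 5 lowest 0 to 2 against 11 to 23. The median ratio of resting Th1 to naive was 1.60, a shift of 0.68 on the log2 scale. Relative to that median, 560 regions were higher and 379 lower, so the near absence of lower regions depended on the scaling.

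Resting Th2 cells differed from naive cells in much the same way, with 1835 higher and 91 lower regions among 8824. Simulated pairs without any difference gave 156 calls in both directions together, so many of the 91 may be calls of that kind. The highest was on chromosome 19, 10379201 to 10379600, with 64 reads in resting Th2 and 3 in naive, a ratio of 33.0 (10.8 to 164). On chromosome 12, 35808201 to 35808600, resting Th2 had 22 reads, resting Th1 14 and naive 0, at least 11.3-fold higher in resting Th2 than in naive (exact lower bound 8.47). On chromosome 16, 50289601 to 50290400, resting Th2 had 30 reads, naive 1 and resting Th1 2. Naive was the higher library on chromosome 11, 97589601 to 97590000, with 20 reads against 1, a ratio of 12.9 (2.07 to 536). The 5 highest regions had 20 to 64 reads in resting Th2 against 0 to 3 in naive, and the 5 lowest 0 or 1 against 12 to 20. The median ratio was 1.70, a log2 shift of 0.77, and relative to it 796 regions were higher and 528 lower.

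The same regions were often higher than naive in both resting subsets: 594 of 7660 regions tested in both comparisons were higher in both. Independent lists of the same lengths would share 128, and simulated unchanged libraries shared 8.32 on average. Numbers for independent lists, here and below, take all tested regions as equally likely to be called. Calling depends on the number of reads, so part of an excess over them may come from that. Both comparisons use the naive library, so part of the excess may come from it, and with 1 naive library it could not be split. Lower regions shared by both numbered 12, against 0.867 for independent lists and 7.96 for simulated unchanged libraries. Relative to the median ratios, the shared regions numbered 174 higher and 152 lower, so the near absence of shared lower regions depended on the scaling.

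Fewer regions differed between resting Th1 and resting Th2 cells, with 230 regions higher in Th1 and 540 higher in Th2 among 10941. The region most in favour of Th2 was on chromosome 9, 57875601 to 57876000, with 16 reads in resting Th2 and 0 in resting Th1, at least 7.19-fold higher (exact lower bound 5.2); stimulated Th2 had 44 reads there and stimulated Th1 14. The region on chromosome 16 from 50289601, named above, had 20.2-fold more RPM in resting Th2 than in resting Th1 (5.13 to 175). On chromosome 15, 66594201 to 66594400, resting Th2 had 13 reads and stimulated Th2 20, against 0 in resting Th1 and 1 in stimulated Th1. Regions in favour of Th1 lay on chromosome 15, 93744001 to 93744200, with 19 reads against 0, at least 4.69-fold higher (exact lower bound 3.46), and 93804801 to 93805200, with 23 against 1. The 5 regions most in favour of Th1 had 19 to 45 reads against 0 to 5, and the 5 most in favour of Th2 had 13 to 30 against 0 to 2. The median ratio of Th1 to Th2 was 0.900, a log2 shift of -0.15, and relative to it 345 regions were higher in Th1 and 357 in Th2, an even split. Simulated unchanged libraries gave 199 calls, against 770 here. The simulation leaves out that regions were called on reads that were then counted, so 199 may be too low a reference.

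Stimulation in Th1 cells gave 5447 differing regions, the most of the 8 comparisons under the main rule. The rank was not stable: activation in Th2 had more with all reads kept (11985 against 11407), Th17 against Th1 had more with regions called on 50% of the reads and counted on the other 50% (1615 against 1587), and both Th17 comparisons had more under the 2-fold rule (8473 and 7993 against 6283). Of 18825 regions tested there, 4548 were higher after stimulation and 899 lower. In Th2 cells, 2783 of 19427 were higher and 984 lower. The top region was the same in both subsets: chromosome 12, 114035801 to 114036600, with 197 reads in stimulated Th1, 128 in stimulated Th2, 141 in stimulated Th17, 12 in input and 0 in naive, resting Th1 and resting Th2. That is at least 30.3-fold higher in stimulated than in resting Th1 (exact lower bound 24.4) and at least 13.4-fold in Th2 (10.8). On chromosome 14, 121309601 to 121310000, stimulated Th1 had 131 reads and resting Th1 0, at least 20.2-fold higher (exact lower bound 16.2). On chromosome 5, 31879001 to 31879400, stimulated Th2 had 121 reads and resting Th2 1, a ratio of 38.1 (6.70 to 1515). In these regions the resting library lay below the input, which had 3.40, 1.70 and 3.96 RPM in that order. Resting Th2 had 0.746 RPM in the last. A lack of reads in the resting libraries, taken up below, thus bears on these folds. Regions that were lower after stimulation included chromosome 2, 32493601 to 32493800, with 28 reads in resting Th1 and 2 in stimulated Th1, 30.3-fold lower (7.65 to 263). On chromosome 4, 10697201 to 10697400, reads fell from 27 to 6 in Th2, 14.3-fold lower in RPM (5.79 to 42.4), with 24 reads in resting and 7 in stimulated Th1. The 5 highest regions had 94 to 197 stimulated reads against 0 at rest in Th1, and 72 to 128 against 0 or 1 in Th2.

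**Figure D2:**
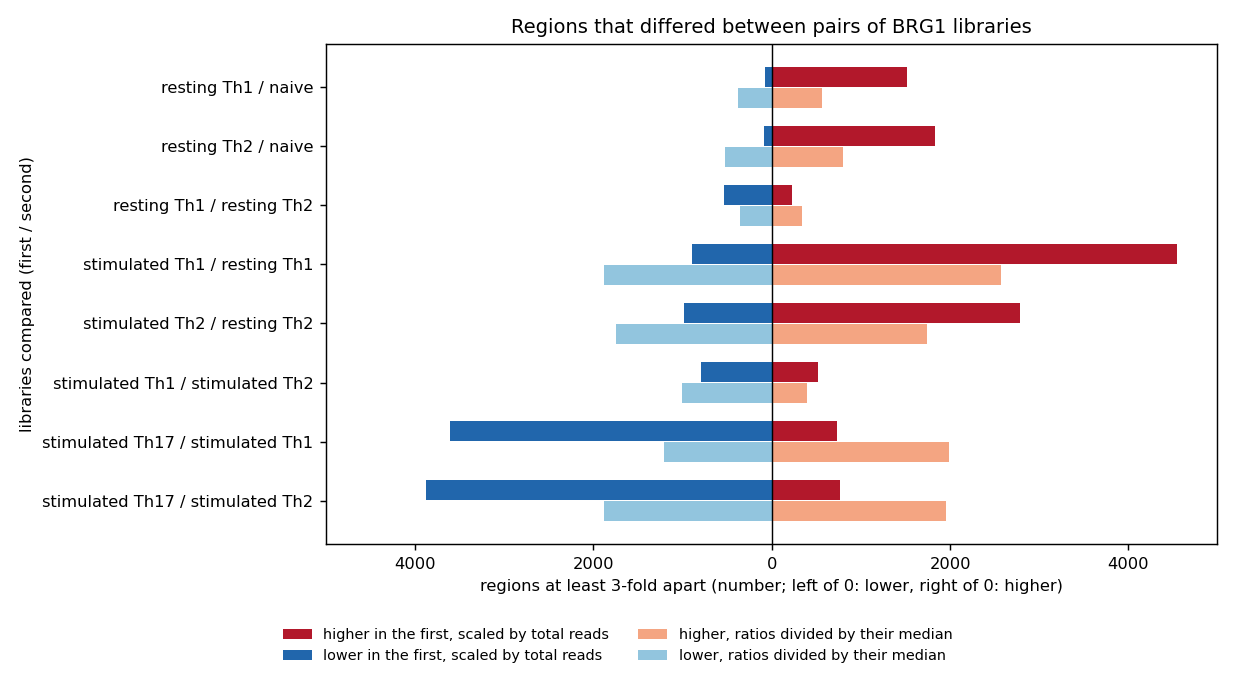
The number of regions at least 3-fold higher (right) or lower (left) in the first library of each pair, scaled by total reads (dark bars) or after division by the median ratio (light bars). Stimulated against resting Th1 has the most higher regions, 4548, or 2570 relative to the median ratio of 1.50. For stimulated Th17 the larger side changes with the scaling.

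The changes overlapped between Th1 and Th2, in comparisons that have no library in common. Of 16471 regions tested in both, 1915 were higher after stimulation in both subsets, against 599 for independent lists, and 195 were lower in both, against 21.7. These references again take all tested regions as equally likely to be called. Only 4 regions moved in opposite directions. The resting libraries were also empty together. Of 14519 blocks of 1 kb with at least 8 input reads, 538 had no read in either resting Th1 or resting Th2. Independent libraries would give 105 if all blocks were equally likely to be empty. Part of the shared higher regions may thus come from a lack of reads common to both. The median ratios were 1.50 in Th1 and 1.26 in Th2, log2 shifts of 0.58 and 0.33. Relative to them, 2570 regions were higher and 1885 lower in Th1, and 1743 were higher and 1744 lower in Th2. In Th2 the excess of higher regions was thus no longer present. In 10 kb bins without regions the ratios were 0.846 in Th1 and 0.923 in Th2, so scaling by these raises the ratios instead. At equal depth the median ratios were 1.27 in Th1 and 1 in Th2, and relative to them 1499 regions were higher and 747 lower in Th1, and 1383 higher and 509 lower in Th2.

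Many of the higher regions had no read at all at rest: 2064 of the 4548 in Th1 and 1297 of the 2783 in Th2. In these regions the unstimulated libraries that were not used to choose them were also low. In the Th1 set, the pooled read density over the input was 0.762 in naive (0.717 to 0.809) and 1.50 in resting Th2. In the Th2 set it was 0.675 in naive (0.628 to 0.725) and 0.985 in resting Th1 (0.923 to 1.05). Across all tested regions of the Th1 comparison it was 2.38 in naive and 4.13 in resting Th2. Every BRG1 library had more empty blocks than the input predicts: of the 14519 blocks of 1 kb, 1227 were empty in naive where 54.3 were expected, 1144 in resting Th1 (103 expected), 1331 in resting Th2 (328), 307 in stimulated Th1 (0.686), 233 in stimulated Th2 (0.308) and 71 in stimulated Th17 (7.29e-05). The blocks were chosen for a high input count, and the same count set the expectation. Part of this excess therefore follows from the choice of blocks, and how much is not known. With only regions where both libraries held at least 0.5 times the input density, an alternative chosen after the data were examined that by its construction drops regions without resting reads where the input has reads, 2747 were higher and 881 lower in Th1, and 1605 higher and 978 lower in Th2.

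**Figure D3:**
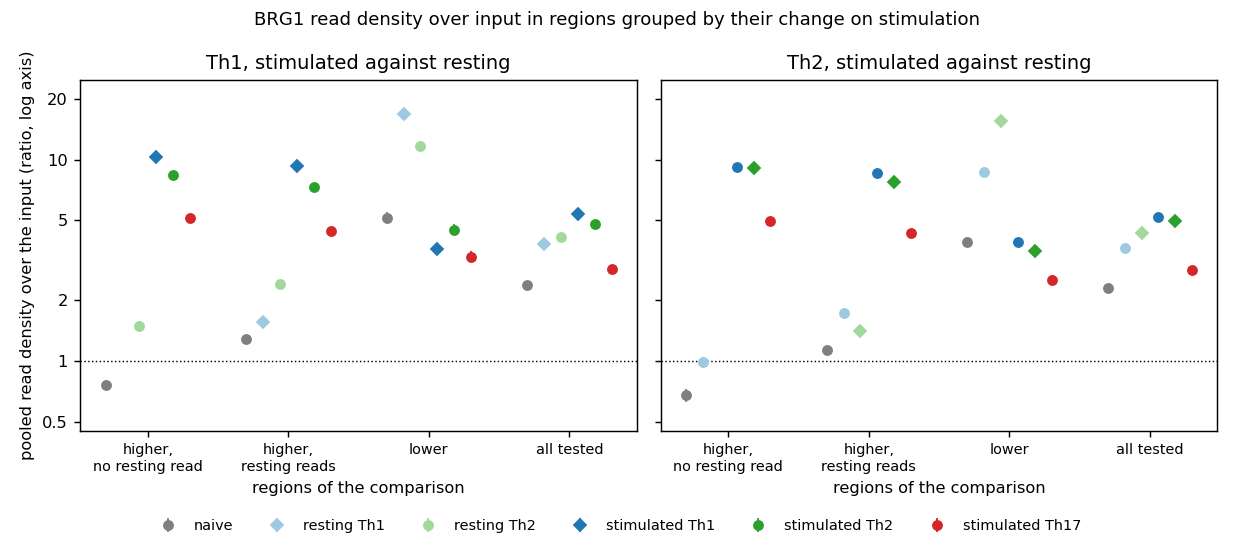
Read density pooled over regions and divided by that of the input (log axis), per BRG1 library, with 95% intervals for counting error that are mostly smaller than the symbols; diamonds mark the 2 libraries that chose the regions, and the dotted line is the input. In regions higher after stimulation without a resting read, the other unstimulated libraries lie between 0.675 and 1.50, and the stimulated libraries between 4.99 and 10.3; the library with 0 reads is not drawn.

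Stimulated Th1 and Th2 cells had the most similar libraries by correlation, with 518 regions higher in Th1 and 788 higher in Th2 among 21658. The region most in favour of Th1 was on chromosome 17, 74218801 to 74219000, with 41 reads in stimulated Th1 and 3 in stimulated Th2, a ratio of 14.9 (4.74 to 75.1). On chromosome 14, 122229201 to 122229600, the counts were 54 and 8, a ratio of 7.34 (3.47 to 17.9). In favour of Th2, chromosome 2, 80302001 to 80302400, had 49 reads in stimulated Th2 and 2 in stimulated Th1, 22.5-fold more RPM (5.91 to 191), and 17 against 1 at rest. On chromosome 12, 15723201 to 15723400, stimulated Th2 had 26 reads, resting Th2 6, stimulated Th17 1 and stimulated Th1 0, at least 7.97-fold higher in stimulated Th2 than in Th1 (exact lower bound 6.03). The 5 regions most in favour of Th1 had 13 to 54 reads against 0 to 8, and the 5 most in favour of Th2 had 26 to 49 against 0 to 2. The median ratio of Th1 to Th2 was 1.09, a log2 shift of 0.12, and relative to it 399 were higher in Th1 and 1002 in Th2. At equal depth the larger side changed, to 289 higher in Th1 and 199 in Th2.

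Differences between Th1 and Th2 recurred in both states, again in pairs without a shared library. Of 10235 regions tested at rest and after stimulation, 67 were higher in Th2 in both, against 6.83 for independent lists, and 10 were higher in Th1 in both, against 1.51. The same limit of independent lists holds here. With regions called on 50% of the reads and counted on the other 50%, the shared regions numbered 4 for Th2 and 0 for Th1. Libraries of the same subset were empty in the same 1 kb blocks more often than independent libraries. The blocks numbered 146 against 24.2 in Th1 and 133 against 21.4 in Th2. This was not particular to a subset: resting Th1 and resting Th2 shared 538 empty blocks against 105, and naive and resting Th2 472 against 112. No resting library was compared in this way with a stimulated library of the other subset. A region was on opposite sides in 1 case each way. Of the 499 regions higher in resting Th2, 18.6% (15.3 to 22.3) had a stimulated Th1 to Th2 ratio above that comparison's median, against 64.3% (57.1 to 71.0) of the 196 higher in resting Th1 and 44.8% of all. Among the strongest of the 67 were chromosome 2 from 80302001, named above, and chromosome 13, 118049601 to 118050000, with 12 reads against 0 at rest and 22 against 1 after stimulation. Among those shared by Th1 was chromosome 17 from 74218801, with 17 reads against 2 at rest.

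**Figure D4:**
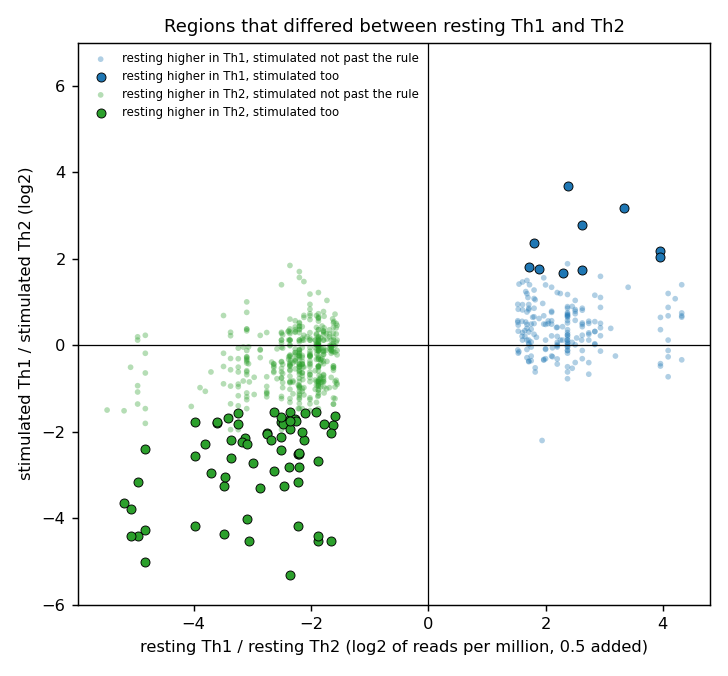
Log2 ratio of Th1 to Th2 RPM, 0.5 reads added, in stimulated libraries (vertical) against resting libraries (horizontal), for the 196 regions higher in resting Th1 (blue) and the 499 higher in resting Th2 (green). Outlined points passed the same rule in the stimulated libraries, 10 for Th1 and 67 for Th2.

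Stimulated Th17 cells had lower BRG1 read density than stimulated Th1 and Th2 cells in most regions that differed, when scaled by total reads. Against stimulated Th1, 735 regions were higher in Th17 and 3607 lower among 22139. Against stimulated Th2, 764 were higher and 3876 lower among 22829. Stimulated Th17 was the deepest library, and far fewer regions differed in both comparisons at equal depth, as given below. The regions highest in Th17 included chromosome 17, 5255401 to 5255800, with 67 reads in stimulated Th17 and 1 in stimulated Th1, a ratio of 33.3 (5.77 to 1333), and 12 in stimulated Th2. On chromosome 1, 20750001 to 20750200, the counts were 58 and 1, and on chromosome 3, 94187601 to 94187800, they were 38 and 0, at least 6.29-fold higher (exact lower bound 4.87). Against Th2, chromosome 17, 8427401 to 8427800, had 42 reads and 0, at least 7.56-fold higher (exact lower bound 5.88), and chromosome 7, 72911601 to 72912000, had 52 and 1. On the lower side, chromosome 11, 51269001 to 51269400, had 1 read in stimulated Th17 against 41 in stimulated Th1, 82.6-fold lower (14.0 to 3341), and 48 in stimulated Th2, with 19 to 30 in the unstimulated libraries. The 5 highest regions in Th17 had 36 to 67 reads against 0 or 1 in Th1, and 29 to 52 against 0 or 1 in Th2.

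The larger side of the Th17 comparisons changed on division by the median ratio, but not every scaling moved it that way. In 10 kb bins without regions the ratios were 1.08 to Th1 and 1.05 to Th2, so scaling by these lowers the Th17 ratios slightly further. The median ratios were 0.579 to Th1 and 0.623 to Th2, log2 shifts of -0.79 and -0.68. Relative to them, 1986 regions were higher in Th17 than in Th1 and 1203 lower, and 1954 were higher than in Th2 and 1882 lower. In total 312 regions were higher in Th17 than in both others, against 26.0 for independent lists and 6.29 for simulated unchanged libraries that share the Th17 library, and 1957 were lower than in both, against 456 and 9.24. Relative to the median ratios these numbers were 1059 higher and 732 lower, so the larger side changed. Part of both excesses may come from the shared library, of which there was 1.

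Regions higher in a stimulated subset than in both others numbered 227 for Th1, 520 for Th2 and 312 for Th17, or 79, 457 and 1059 relative to the median ratios. The resting libraries, which did not choose the direction but helped to define the union regions, were read in the same regions. They are thus not an independent check. Over all regions tested between the resting libraries, the median ratio of Th1 to Th2 was 0.900. The regions higher in stimulated Th2 had 3.65-fold more RPM in resting Th2 than in resting Th1 (3.36 to 3.98). Those higher in stimulated Th1 had 1.62-fold more in resting Th1 (1.38 to 1.90). Those of Th17 had a ratio of 1.06 (0.858 to 1.32), with no difference detectable at this depth.

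A few of these regions lay close together. Th17 had 4 clusters of at least 3 regions, where random sets of tested regions gave 0.4 on average; Th2 had 4, against 1.48, and Th1 had 1, against 0.18. Among the random sets the most clusters were 2 for Th17, 5 for Th2 and 2 for Th1, so only the Th17 number lay above all of them. The cluster with the most regions was on chromosome 17, 8402801 to 8435600. Its 5 regions held 204 reads in stimulated Th17, or 25.8 RPM, against 4.08 RPM in stimulated Th1, 2.35 in stimulated Th2 and 1.13 in input. On chromosome 11, 53418801 to 53470600, 4 regions held 24.4 RPM in stimulated Th2, against 5.87 in stimulated Th1 and 5.45 in stimulated Th17. At rest these 4 regions held 26.9 RPM in Th2 and 8.30 in Th1, a ratio of 3.24 (1.73 to 6.37). Between them, the bin from 53449001 to 53450000 held 88 reads in stimulated Th1, 74 in stimulated Th2 and 84 in stimulated Th17, and 1, 0 and 1 in resting Th1, resting Th2 and naive; the input had 10 there, or 2.83 RPM, above the unstimulated libraries. The Th1 cluster lay on chromosome 9, 44866801 to 44887400, with 21.2 RPM in stimulated Th1, 5.40 in stimulated Th2 and 4.18 in stimulated Th17.

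**Figure D5:**
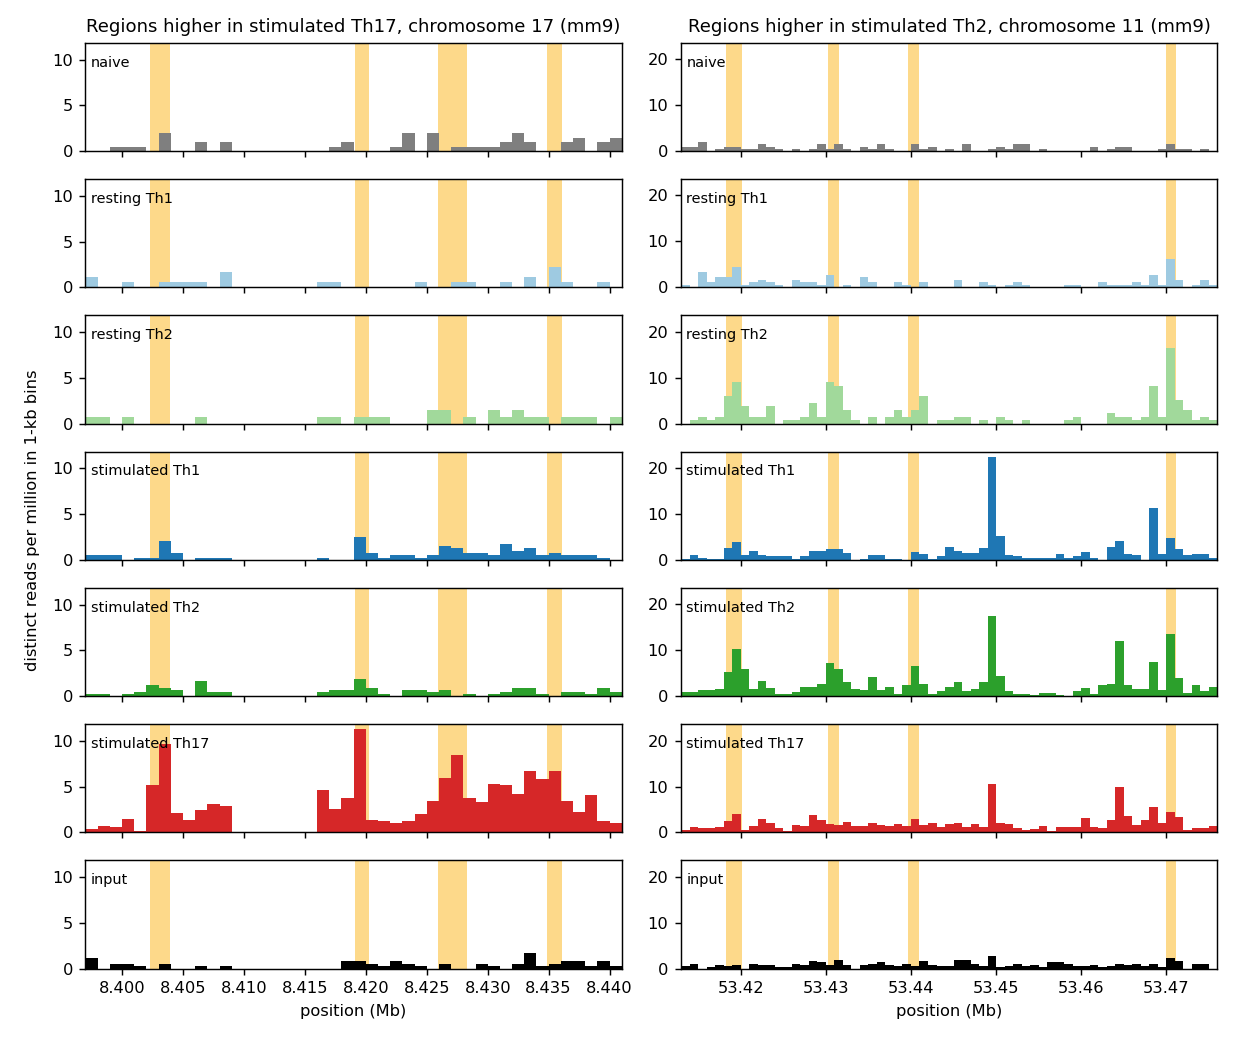
RPM of distinct reads in bins of 1 kb across the Th17 cluster and the Th2 cluster with the most regions of their subset, on mm9: left, chromosome 17 around 8402801 to 8435600, right, chromosome 11 around 53418801 to 53470600, 1 row per library. Yellow bands mark the 5 regions higher in stimulated Th17 and the 4 higher in stimulated Th2 than in both other stimulated libraries, widened slightly to be visible.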

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

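The test of a single enrichment factor, the test of lost sequences, the opposite regions and the ratios by distance from the Th2 regions were chosen after the results were seen. Counting at equal depth was added after the data were examined, with its outcome still unseen.

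A handful of regions moved in opposite directions on stimulation in Th1 and Th2 cells, which is what drew attention to them; the difference between the subsets was not tested. On chromosome 4, 88862801 to 88863000, Th1 had 14 stimulated and 0 resting reads while Th2 had 4 and 6, a log2 activation ratio 5.94 higher in Th1 with 0.5 reads added. On chromosome 6, 15671201 to 15671400, the counts were 15 and 0 in Th1 and 8 and 9 in Th2, a log2 difference of 5.67. On chromosome 6, 108618401 to 108618600, they were 21 and 2 in Th1 and 6 and 9 in Th2, a difference of 4.21. On chromosome 19, 29260201 to 29260600, they were 11 and 0 in Th1 and 11 and 11 in Th2, a difference of 5.08. Independent lists of the same lengths would give 149 regions of this kind, so these 4 are far fewer than chance pairing gives. Where resting Th1 had 0 reads the log2 values depend on the 0.5 reads added; against the floor of 3 counts, the rise in Th1 was at least 2.15-fold, 2.31-fold and 1.69-fold in the 3 regions on chromosomes 4, 6 (from 15671201) and 19, with exact lower bounds of 1.53, 1.66 and 1.16.

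A first pattern is the excess of regions higher after activation, 4548 in Th1 and 2783 in Th2. The values argue against library depth as the whole cause, since at equal depth 1383 of 10993 tested regions were higher in Th2, the comparison with fewer, and 509 lower, where 20 simulated unchanged pairs of that depth gave 108 higher on average and 128 at most. A single factor of enrichment for all regions cannot be told apart from a change on stimulation: after division by the median ratio, 57.7% of differing regions in Th1 and 50.0% in Th2 were higher with all distinct reads, and 66.7% and 73.1% at equal depth, where the median ratio in Th2 was 1 and the division changed nothing. That share thus moves with depth, and the share that such a factor would give is not known. Sequences lost from the unstimulated libraries cannot be told apart from a change on stimulation either. Over all higher regions, the unstimulated libraries not used to choose them held 1.14 (naive) and 2.17 (resting Th2) times the input density in the Th1 set, and 1.00 (naive, 0.968 to 1.04) and 1.51 (resting Th1) in the Th2 set, each below its density over all tested regions, as a partial loss and a change on stimulation would both give. Stimulation itself stays open as a biological explanation, untested against the repeated reads, 28.5% to 41.4% in unstimulated and 10.2% to 11.8% in stimulated libraries.

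A second pattern is the 67 regions higher in Th2 than in Th1 both at rest and after stimulation. Regions picked for high counts in the Th2 libraries were tested by calling on 50% of the reads and counting on the other 50%, where the shared regions numbered 4 against 0.301 for independent lists, which argues against that choice as the whole cause, on few regions. Regional bias or copy number is a candidate explanation, for part of the difference, that the test set beforehand favours. The 10 kb on each side, outside regions, were 1.99-fold higher in Th2 at rest and 1.70-fold after stimulation. At 2 to 10 kb the ratios were 1.76 (1.64 to 1.89) at rest and 1.49 (1.43 to 1.55) after stimulation. The latter lay just under the cut of that test, so the outcome of the test depended on reads within 2 kb of the regions. The ratio was 1.51 and 1.33 at 10 to 50 kb and 1.25 (1.22 to 1.27) and 1.16 (1.15 to 1.17) at 50 to 200 kb, while the regions themselves, chosen for their ratio, stood at 7.55 and 5.46. A broad domain of BRG1 binding in Th2 cells may give the same falling profile and stays open, untested.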

How the results depend on the processing

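Equal depth, with or without centring, the filter on input density and all alternatives for shared, subset-specific and common regions were chosen after the data were examined. Depth limits every result: each group has 1 library, and regions with under 10 reads in a pair were not tested. The direction of all 80 named entries stayed, within their intervals, under the 4 alternatives run on them. These were ratios centred on their median, ratios scaled by bins without regions, all reads kept, and 50% of the reads. An entry is a region in a comparison, and some regions were named in more than 1 comparison. The entries were picked as the most extreme of their comparison on the same reads. The alternatives thus had little room to reverse them, and no conclusion on robustness is drawn. Promoter shares, gene list medians and sequence motifs were not run. Leaving out the shift moved no count of regions per library by over 1.5 times, and scaling by bins without regions moved no count of differing regions by that much. Where a cause does not follow from how an alternative is built (fewer reads, a stricter or looser rule), the cause was not tested.

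With all reads of each library, there were 5386 regions in naive, 28166 in stimulated Th1, 31051 in stimulated Th2 and 42466 in stimulated Th17, and the regions held 3.32% of the reads of naive, 6.63% of resting Th1, 17.8% of stimulated Th1, 16.7% of stimulated Th2 and 14.2% of stimulated Th17. At a threshold of 1e-08 there were 881 regions in naive, 2857 in resting Th1, 3442 in resting Th2, 4929 in stimulated Th1, 4158 in stimulated Th2 and 1464 in stimulated Th17, with 97 in all 6. The overlaps were then 59.8% for naive with resting Th1, 56.5% for naive with resting Th2, 47.6% between the resting libraries, 35.8% for resting with stimulated Th1, 32.9% for resting with stimulated Th2, 48.6% between stimulated Th1 and Th2, and 43.6% and 37.2% for Th17 with stimulated Th1 and Th2. With an overlap of 50% required, stimulated Th1 and Th2 shared 46.4%. With the genome mean as background there were 7167 regions in naive, 12023 in resting Th1, 13989 in resting Th2, 18107 in stimulated Th1, 17739 in stimulated Th2 and 11483 in stimulated Th17.

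With all reads kept at repeated positions there were 17064 regions in naive, 18093 in resting Th1, 30306 in resting Th2, 19731 in stimulated Th1, 20867 in stimulated Th2 and 15420 in stimulated Th17, so resting Th2 then had the most. They held 8.12%, 11.7%, 16.4%, 17.6%, 17.6% and 9.92% of the reads in the same order. Differing regions then numbered 6624 for naive against resting Th1, 8743 for naive against resting Th2, 4591 between the resting libraries, 11407 for activation in Th1, 11985 for activation in Th2, 3923 for stimulated Th1 against Th2, and 8741 and 10540 for Th17 against Th1 and Th2.

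In the same order of comparisons, at least 20 reads left 452, 525, 160, 3203, 2402, 571, 2879 and 2861 differing regions. Calling on 50% of the reads and counting on the other 50% left 276, 291, 99, 1587, 767, 326, 1615 and 1493, with 4 regions shared by Th2 at rest and after stimulation and 0 shared by Th1. In stimulated Th1 against Th2 the larger side then changed, to 191 higher in Th1 and 135 in Th2. At equal depth the count moved to 921 for naive against resting Th1, 2401 for activation in Th1, 1892 for activation in Th2, 488 for stimulated Th1 against Th2, 1786 for Th17 against Th1 and 1378 for Th17 against Th2. At equal depth with centring on the median ratio, run for activation only, it was 2246 in Th1 and 1892 in Th2. Under the 2-fold rule it moved to 2127 for stimulated Th1 against Th2 and to 8473 and 7993 for Th17 against Th1 and Th2, with 24 shared Th1 and 105 shared Th2 regions. Requiring 0.5 times the input density moved activation in Th1 to 3628. Centring on the median ratio moved naive against resting Th1 to 939, and the regions higher in a stimulated subset than in both others to 79 for Th1 and 1059 for Th17.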

Other observations

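The sets of regions described here and the test of donor sex were chosen after the results were seen, and the test of chromosome X outside regions was set before its result was seen.

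Regions called only in the 3 stimulated libraries were not empty at rest. These 785 regions held 11.3 times the input density in stimulated Th1, 9.48 in stimulated Th2 and 6.90 in stimulated Th17. They held 2.23 times the input density in resting Th2 (2.11 to 2.36), 1.97 in resting Th1 (1.87 to 2.08) and 1.17 in naive (1.11 to 1.24). The 175 regions called only in the 3 unstimulated libraries held 4.12 times the input density in resting Th1, 4.08 in resting Th2 and 3.32 in naive. They held 1.94 in stimulated Th1, 1.73 in stimulated Th2 and 1.08 in stimulated Th17 (1.03 to 1.15). The 378 regions called in all 6 libraries held between 4.27 times the input density, in stimulated Th17, and 8.37 times, in resting Th2. An example with no input read is chromosome 15, 100012401 to 100012600, with 17 reads in naive, 29 in resting Th1, 12 in resting Th2, 47 in stimulated Th1, 37 in stimulated Th2 and 56 in stimulated Th17.

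Some regions were present in 5 libraries and nearly empty in the sixth, and the sixth was naive or stimulated Th17 each time. Of 640 regions called in the other 5 libraries, 30 had under 0.1 times their pooled rate in naive. For stimulated Th17 these were 4 of 779, and for resting Th1, resting Th2, stimulated Th1 and stimulated Th2 they were 0 of 406, 0 of 406, 0 of 393 and 0 of 415. The cut is easier to reach in naive and stimulated Th17, whose median rates in these regions were 0.66 and 0.52 times the pooled rate of the others, against 1.20 to 1.36 times in the other 4 libraries. The 4 regions low in Th17 lay on chromosomes 3, 7, 11 and 12. On chromosome 3, 141838401 to 141838600, stimulated Th17 had 0 reads, and naive had 18, resting Th1 12, resting Th2 9, stimulated Th1 19 and stimulated Th2 14. On chromosome 12, 49931801 to 49932000, stimulated Th17 had 0 reads and naive 21, resting Th1 10, resting Th2 7, stimulated Th1 20 and stimulated Th2 15, and the input had 0 in both.

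A pattern across whole chromosomes was a lower share of chromosome X reads in the stimulated libraries: 2.20% in stimulated Th17, 2.67% in stimulated Th1 and 2.90% in stimulated Th2, against 4.43% in naive and 4.21% in input. Resting Th1, at 3.95%, and resting Th2, at 3.70%, lay between and also below the input. Reads in called regions are not the whole cause, since outside 10 kb bins with a region the share in stimulated Th17 minus that in the input was still -1.89 percentage points. Outside those bins the shares were 2.83% in stimulated Th17, 3.63% in stimulated Th1 and 3.93% in stimulated Th2, below the 4.72% of the input, and 4.83% in resting Th2, 4.97% in resting Th1 and 5.26% in naive, above it. The sex of the donor animals is a poor candidate explanation, since the share of chromosome Y reads in stimulated Th17 was 0.140 times that in the input (0.110 to 0.176), where fewer X copies in males would go with more Y reads. The other 5 BRG1 libraries were below the input too, from 0.372 times in stimulated Th2 to 0.709 in naive. Autosomes moved too, from 0.833 times the input share on chromosome 3 to 1.26 times on chromosome 11 in stimulated Th17. Base composition was not analysed here and stays open, as does stimulation.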
